A study of Arabidopsis thaliana with 6 samples.

How the data were processed

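Total RNA from unshaded rosette leaves of Arabidopsis thaliana, accession Ws-2 at growth stage 3.90, was labelled with biotin and hybridised to 6 single-channel Affymetrix Arabidopsis arrays of 8297 probe sets, per the labels. The deposited values are intensity values on a linear scale, 1 column per array. On every array the mean after trimming 2% from each end was 100.2, so the deposited values had been scaled to a common level but not quantile normalized, with medians from 20.0 to 26.1. The software that made them is not given in the sources used here. The number of arrays limits the precision, since each code had 1 array.

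The arrays carry the codes CLL, CLM, CLH, CVL, CVM and CVH, which cross 2 starts (CL and CV) with 3 endings (L, M and H). The numbers in the sample titles cross the same way, with 410, 411 and 413 for CL and 140, 141 and 143 for CV. The series concerns acclimation to light intensity, but no label says what the letters stand for, and no light level was assigned to any array. The growth record of the L arrays gives 16 hours of dark and 15 °C in the dark, which the records of the other arrays do not. Nothing says whether plants of different arrays were grown or harvested separately, so the p-values measure only the spread between these arrays. That spread may be technical, and it also holds any difference between the starts in the effect of the endings.

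Values were analysed as log2(value + 3.9), where the offset is the 20th percentile of all deposited values, so that a log2 change understates the change of dim probe sets. The 50 control probe sets were set aside, and the 30% of the remaining probe sets with the lowest mean over the 6 arrays (2474 probe sets, all at or below a mean signal of 8.87) were left out, which left 5773. An additive model with the start and the ending of the code was fitted with limma (version 3.58.1 in R 4.3.3; lmFit, then eBayes with an intensity trend), giving CV against CL, M against L, H against L and H against M. The fit left 2 residual degrees of freedom, and any difference between the starts in the effect of the endings was counted as error. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The changes from L within CL and within CV each compare 2 single arrays and were not tested.

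Probe sets were named from the platform annotation, updated through the gene identifiers of the TAIR10.1 table, from which only names were used. One gene was paired with 3794 probe sets (3792 of them matched to a locus, for 3602 distinct genes), several genes with 70, and no gene was listed for 4383, which are unnamed here. A gene with several probe sets was represented by the one with the highest mean, which left 2422 genes once each. Genes without a symbol are given by their locus.

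Gene lists were tested with camera at a preset correlation of 0.01 in limma, with Benjamini-Hochberg adjustment over the lists of a contrast, and with camera at an estimated correlation and with fry beside it. Before the data were examined, 27 lists had been fixed; 9 of these had at least 3 measured genes and were tested, 7 had 1 or 2, and 11 had none. Because only 37 of their 373 genes were on the array under a name, 15 lists were added from the annotation after the probe table had been opened and before any change between arrays was computed; 14 of them were tested. The added lists are the cytosolic and plastid ribosomal proteins, the pooled photosynthesis genes, dehydrins and late embryogenesis abundant proteins, cell wall enzymes, defence-linked genes, vacuolar ATPase, ATG8, respiratory chain, auxin-linked genes, glycosyltransferases, carboxypeptidases, floral genes, cell division genes and folding proteins. For single-array changes, the median of a list was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression.

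The genes named were chosen by a rule fixed at the same time as the first lists, over probe sets with 1 gene and 1 probe set per gene. For CV against CL it takes the 10 genes per direction with the largest fitted change among those past the test with the same sign at all 3 endings, filled where needed with the genes of the same sign at all 3 endings whose smallest difference was largest. The other contrasts take 5 per direction in the same way over both starts. Within CL and within CV it takes the 5 with the largest change per direction, and the 8 genes with opposite signs in the 2 starts whose smaller change was largest. Of each list it takes up to 4 members with the largest change.

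The fits were tested on simulated data, with 200 probe sets changed by known amounts and variances drawn from the fitted prior. For CV against CL the fit recovered 41 of 60 probe sets changed by 2 on the log2 scale and 6 of 80 changed by 1, with 2 calls among unchanged probe sets. For M against L, H against L and H against M it recovered 31, 35 and 38 of 60 changed by 2, and 3, 2 and 2 of 80 changed by 1. With 1 array left out, which leaves 1 residual degree of freedom, the simulated fit of CV against CL made between 9 and 66 calls among unchanged probe sets. A shift of 0.75 planted in 43 genes of 1 list was called for CV against CL, with 0 other lists. The simulated genes varied independently of each other, so this cannot show how often lists of correlated genes would be called falsely.

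The alternatives tried were quantile normalization, no filter or leaving out the lowest 50% of probe sets, a smaller offset or 4 times the offset, no intensity trend, no block for the other part of the code, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.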

Results

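Transcript levels in rosette leaves of Arabidopsis were measured on 6 arrays in a study of acclimation to light intensity, 1 array for each of the codes CLL, CLM, CLH, CVL, CVM and CVH. The codes give 2 starts with 3 arrays each and 3 endings with 2 arrays each, and there were no replicates of any code. Median signals ran from 20.0 in CVM to 26.1 in CLL, and 5773 probe sets were tested.

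The comparison of CV with CL asks which genes differ between the 2 starts of the code whatever its ending. Genes for cytosolic ribosomal proteins, the structural proteins of the ribosome, were higher in CV, with 42 of 43 members on that side and a median log2 change of 0.76. All 6 measured ATG8 genes, which encode the ubiquitin-like proteins of autophagosome membranes, were lower in CV (median -0.74), and so were all 4 measured genes of the cold, drought and abscisic acid list (median -1.24). All 5 antioxidant enzyme genes were higher in CV (median 0.45), as were 21 of 33 photosynthesis and plastid pigment genes (median 0.15). Larger differences were seen in single genes that did not pass the test: the signal of GSTF3, a glutathione transferase, averaged 71.1 over the 3 CV arrays and 310.8 over the 3 CL arrays, and that of THI2.1, a thionin, 39.7 in CV and 4.50 in CL. The THI2.1 signal in CL was near the offset of 3.9, and its other 2 probe sets did not share the difference, with changes of 0.06 and 0.56.

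In the ribosomal list the largest change was that of AT4G17390, which encodes a protein of the large subunit, at 1.65 (SE 0.27, 3 arrays against 3), followed by AT2G44120 (1.15, SE 0.32), AT2G47610 (1.15, SE 0.34) and AT2G41840 (1.15, SE 0.25). No member passed the test over all probe sets, and 26 passed it adjusted over the list alone, all 26 higher in CV. The median difference between CV and CL in this list was 0.87 at L, 1.28 at M and 0.21 at H, with 42, 42 and 32 of the 43 genes higher in CV. Relative to each gene's mean, the median of the list was between -0.44 and -0.34 on the 3 CL arrays, 0.49 on CVL, 0.84 on CVM and -0.12 on CVH. The 2 measured members of the plastid ribosomal list had changes of 0.72 (AT4G01310, SE 0.25) and 0.62 (AT2G43030, SE 0.23).

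**Figure D1:**
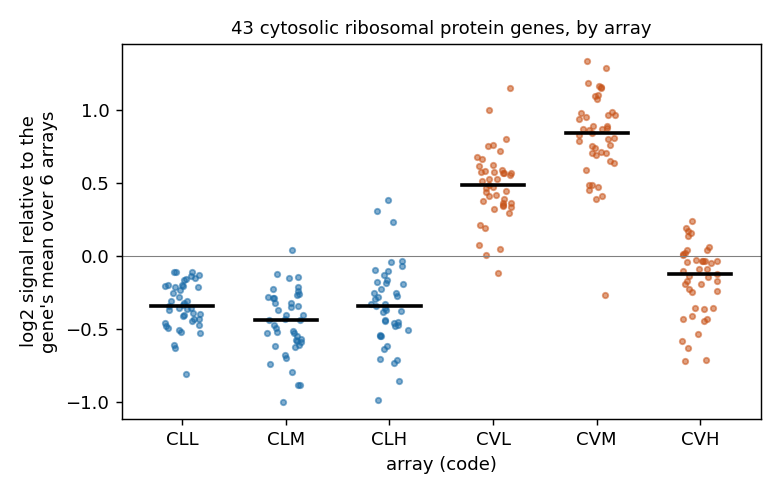
Log2 signal of 43 cytosolic ribosomal protein genes on each array, relative to each gene's mean over the 6 arrays (points, 1 per gene; black bars, medians). The medians lie at -0.34, -0.44 and -0.34 on the CL arrays and at 0.49, 0.84 and -0.12 on CVL, CVM and CVH.

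The median difference of the ATG8 list was -0.78 at L, -1.12 at M and -0.31 at H, with 6, 5 and 4 of the 6 genes lower in CV. Among its genes, ATG8E changed by -1.93 (SE 0.47), ATG8D by -0.94 (SE 0.26), ATG8F by -0.84 (SE 0.29) and APG8A by -0.65 (SE 0.26). In the cold, drought and abscisic acid list, the dehydrin genes LTI30 and COR47 had changes of -1.43 (SE 0.78) and -1.32 (SE 0.45), STZ, which encodes a zinc finger protein, -1.16 (SE 0.28), and KIN2 -0.31 (SE 0.21). Both dehydrin genes were higher in CV at L and lower at M and H, and at L 3 of the 4 genes of this list were higher in CV. In the antioxidant list the largest changes were those of AT3G11630, a 2-Cys peroxiredoxin (0.75, SE 0.19), and of SAPX, the stromal ascorbate peroxidase (0.62, SE 0.28), followed by GR1, a glutathione reductase (0.45, SE 0.28), and TAPX, the thylakoid ascorbate peroxidase (0.23, SE 0.24). Of the pooled photosynthesis genes, LHCB4.3, a minor antenna protein of photosystem II, changed by 1.15 (SE 0.57), GSA1, an enzyme of tetrapyrrole synthesis, by 1.07 (SE 0.24), AT1G77090 by 0.86 (SE 0.29) and the thioredoxin reductase gene NTRC by 0.71 (SE 0.25). Adjusted over the list alone, 3 ATG8 genes, 2 genes of the cold list and 1 antioxidant gene passed.

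These 5 lists were the ones called by camera, with adjusted p = 2.07e-28 for the ribosomal list, 0.0039 for ATG8, 0.0042 for the photosynthesis list, 0.012 for the antioxidant list and 0.015 for the cold list. With an estimated correlation each of the 5 had adjusted p = 0.726, and fry called 0 lists. The photosynthesis list was not called after quantile normalization (adjusted p = 0.109), its median had percentile 94.1 among random lists, and at M 16 of its genes were higher in CV and 17 lower (median -0.08). Of these lists, the antioxidant and cold lists had been fixed beforehand and the other 3 were added.

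Over all probe sets, limma called 2, both lower in CV and both unnamed here, with log2 changes of -2.40 (SE 0.25, adjusted p = 0.025) and -2.28 (SE 0.22, adjusted p = 0.025). At an unadjusted p under 0.05 there were 748 probe sets, against 288.65 by chance, and 2016 probe sets (34.9%, against 25% by chance) had the same sign at all 3 endings. None of the named genes passed the test, so the following were taken for their smallest difference over the endings. On the higher side in CV were THI2.1 (2.39, SE 0.41), AT3G47342 (1.77, SE 0.33), AT4G17390, AT2G34360 (1.13), GSA1, AT2G37660 (1.07), AT4G02530 (0.94), AT2G33180 (1.12), AT2G35040 (1.06) and AT4G17560 (1.06). On the lower side were GSTF3 (-2.11, SE 0.26, adjusted p = 0.064), the peroxidase gene AT2G18150 (-2.26, SE 0.31, adjusted p = 0.076), AT1G34200 (-1.44), AT1G03740 (-1.73), AT4G28400 (-1.49), AT1G34300 (-1.55), AT5G59170 (-1.43), the linker histone gene HIS1-3 (-1.31), AT1G20880 (-1.31) and AT2G22660 (-1.68). Signals in CVL, CVM and CVH were 5, 4 and 1.5 for AT1G34200 and 3.2, 3.7 and 1.8 for AT1G34300, near or below the offset of 3.9. Those of AT1G03740 were near or below it in CVL (3.4) and CVH (4.4), but not in CVM (13.1). The sizes of the changes of AT1G34200, AT1G34300 and AT1G03740 are therefore uncertain.

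**Figure D2:**
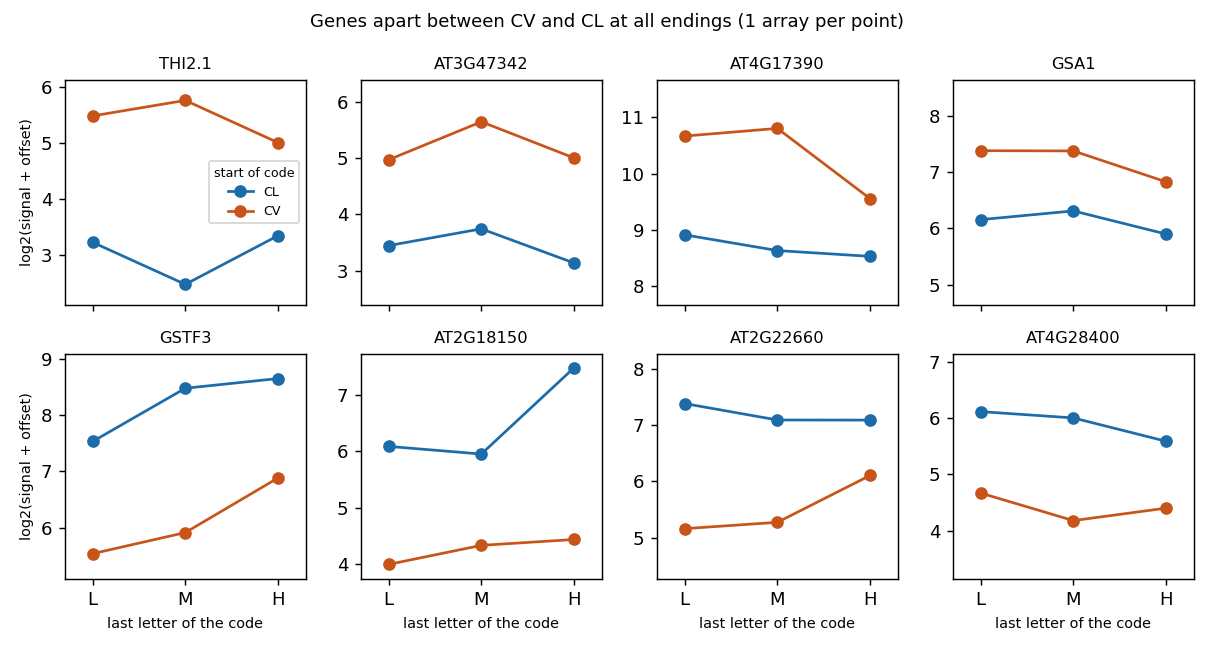
Log2(signal + 3.9) of 8 genes by the last letter of the code (L, M, H) in CL (blue) and CV (orange), 1 array per point. In the upper row CV lies above CL at every ending, and in the lower row below it; the fitted changes range from -2.26 for AT2G18150 to 2.39 for THI2.1.

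The 2 calls were lost without the intensity trend and without the block (0 calls each), and with 5 arrays the count was 251 without CLL, 257 without CVL, 55 without CLH, 57 without CVH and 1 without CLM or CVM, with 1 residual degree of freedom; neither of the 2 calls was kept without CLM or without CVM. Start and array processing cannot be told apart, because the labels give no batch.

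M against L asks which genes differ between these endings in both starts alike. Named genes with a higher level at M in both starts were AT2G32020 (1.72, SE 0.55, 2 arrays against 2), AT4G23590 (1.97, SE 0.67), AT2G22510 (1.76, SE 0.68), the glycosyltransferase gene UGT73C1 (1.34, SE 0.48) and AT2G35540 (1.35, SE 0.58). On the lower side were AT2G14900 (-1.97, SE 0.45), AT1G26930 (-1.36, SE 0.68), AT5G07230 (-1.54, SE 0.46), AT4G36180 (-1.24, SE 0.64) and AT2G41050 (-0.92, SE 0.60). Each had adjusted p = 0.999. CVL signals were below the offset of 3.9 for AT2G32020 (3.6), AT4G23590 (3.3), UGT73C1 (2.6) and AT2G35540 (2). So were the CLL signals of AT4G23590 (1.5) and AT2G35540 (2.7), and the CVM signals of AT2G14900 (3.3) and AT1G26930 (2). The sizes of the changes of these genes are therefore uncertain. In the fit over both starts, the 4 photosystem core genes were higher at M (median 0.35), among them PSAE-1 (0.37, SE 0.18), PSBW (0.37, SE 0.18), PSAN (0.33, SE 0.26) and PSBY (0.18, SE 0.19), as were 34 of 43 ribosomal protein genes (median 0.15), among them AT2G37600 (0.37, SE 0.38) and AT2G45710 (0.32, SE 0.59), and 24 of 33 pooled photosynthesis genes (median 0.05, percentile 61.9 among random lists). Between single arrays the last 2 lists differed between the starts, which was not tested. At M 17 of the 43 ribosomal genes were higher in CL (median -0.09) and 39 in CV (median 0.35), and 26 of the 33 photosynthesis genes were higher in CL and 14 in CV.

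Camera called these 3 lists for M against L, with adjusted p = 0.0089, 0.019 and 0.022. With an estimated correlation the adjusted p were 0.709, 0.735 and 0.709, and after quantile normalization 0 lists were called. Over all probe sets limma called 0, with 74 at an unadjusted p under 0.05 against 288.65 by chance, and 41.5% of probe sets had the same sign in both starts against 50% by chance. Without CLL the count was 16 and without CVL 38, with 1 residual degree of freedom.

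H against L compares the remaining ending with L. The auxin-linked list was higher at H, with 7 of 9 genes on that side (median 0.52): ARL, a gene of organ growth, by 1.52 (SE 0.34), AT2G18010, of the small auxin-up RNA family, by 1.23 (SE 0.61), IAGLU, an auxin glucosyltransferase, by 1.16 (SE 0.28), and IAA20 by 0.68 (SE 0.30). All 4 photosystem core genes were higher at H (median 0.39), and 38 of 43 ribosomal protein genes were lower (median -0.27), among them AT4G10450 (-0.93, SE 0.41), AT2G44120 (-0.91, SE 0.40) and AT4G17390 (-0.75, SE 0.33). Between single arrays, 41 of the 43 ribosomal genes were lower at H than at L in CV (median -0.66) and 19 in CL (median 0.02), a difference between the starts that was not tested.

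Camera called these lists with adjusted p = 0.0049 for the auxin-linked, 0.043 for the photosystem core and 5.15e-05 for the ribosomal list. With an estimated correlation the adjusted p were 0.678, 0.678 and 0.708, and the photosystem list was not called after quantile normalization (adjusted p = 0.991). Adjusted over the list alone, 2 auxin-linked genes, 1 antenna gene and 1 glutathione transferase gene passed, all higher at H. Limma called 0 probe sets, with 349 at an unadjusted p under 0.05. Named genes higher at H were AT1G54070 (1.81), AT4G10700 (1.74), AT4G27360 (1.75, SE 0.32, adjusted p = 0.61), AT2G35540 (1.51) and AT4G26095 (1.88, SE 0.45), and lower ones were AT2G46230 (-1.91, SE 0.44), AT4G19110 (-1.89, SE 0.41), AT4G39570 (-1.89), AT5G07230 (-1.69) and AT4G24060 (-1.70). At L, the signals of AT4G10700 (1.8 in CLL) and AT2G35540 (2.7 in CLL, 2 in CVL) were below the offset of 3.9. At H, those of AT4G39570 (1.1 in CLH, 1.7 in CVH), AT4G24060 (2.1 in CLH) and AT2G46230 (3.7 in CVH) were below it. The sizes of the changes of these genes are therefore uncertain. With 1 array left out the count was 64 without CLL, 54 without CVL, 3 without CLH and 2 without CVH. The ratio of 3-prime to 5-prime GAPDH signal, a measure of RNA quality, was 6.22 in CLH and 5.50 in CVH and at most 3.76 on the other arrays, so differences of H from L or M go together with it in both starts.

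Between H and M, 42 of 43 ribosomal protein genes had a lower fitted level at H (median -0.42), the only list called (adjusted p = 6.32e-12; adjusted p = 0.851 with an estimated correlation). Within CV 42 of the 43 were lower at H than at M (median -0.97), whereas within CL 29 were higher (median 0.13), a difference that was not tested. The largest fitted changes were those of AT4G10450 (-0.97, SE 0.41), PGY1 (-0.84, SE 0.31), AT2G44120 (-0.82, SE 0.40) and AT4G16720 (-0.75, SE 0.35). Adjusted over the list alone, 2 auxin-linked genes passed, both higher at H. Named genes higher at H were AT2G34190 (2.06, SE 0.47), AT2G16835 (2.02, SE 0.37), AT1G65180 (1.40), AT4G26095 (1.49) and ARL (1.77, SE 0.34), and lower ones were AT2G45670 (-1.70, SE 0.41), AT4G39570 (-1.68), AT1G10690 (-1.69), the zinc finger gene ZAT7 (-1.41) and AT2G19400 (-1.50). At M, the signals of AT2G34190 (3.6 in CVM) and AT1G65180 (2.8 in CLM, 3 in CVM) were below the offset of 3.9. At H, those of AT4G39570 (1.1 in CLH, 1.7 in CVH), ZAT7 (1.6 in CVH) and AT2G19400 (2.3 in CVH) were below it. That of AT2G45670 in CVH (3.9) was equal to it. The sizes of the changes of these genes are therefore uncertain. Limma called 0 probe sets, with 256 at an unadjusted p under 0.05; the counts were 9 without CLL, 10 without CVL and 3 without CLH. AT2G16835 and ARL were among those called when CLL or CVL was left out (adjusted p = 0.0075 and 0.0098 for each).

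Within each start, single arrays were compared to see whether the endings differ in the same or the opposite way in CL and CV. Several genes had large changes of opposite sign. AT3G15450 had a signal of 17.2 in CLL, 430.5 in CLM and 200.2 in CLH, and of 113.4 in CVL, 5.40 in CVM and 8.50 in CVH. PORB, a protochlorophyllide reductase of chlorophyll synthesis, went from 306.6 in CLL to 1470.0 in CLM and 925.7 in CLH, and from 1475.6 in CVL to 429.3 in CVM and 343.9 in CVH. LHCB4.3 ran the other way, with 1103.1, 514.6 and 247.5 in CLL, CLM and CLH and 632.0, 1316.0 and 1875.5 in CVL, CVM and CVH. DFR, an enzyme of anthocyanin synthesis, had signals of 44.7, 14.1 and 10.6 in CL and of 3.00, 5.30 and 39.6 in CV.

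The 8 genes with the largest opposite changes from L to M were AT3G15450 (log2 4.36 in CL, -3.66 in CV), LTI30 (2.76, -1.99), the expansin gene EXPA8 (1.80, -2.85), PORB (2.25, -1.77), AT2G07140 (1.55, -1.84), AT2G27420 (-1.65, 1.53), AT3G48230 (-1.50, 1.61) and AT1G27210 (1.63, -1.44). From L to H they were AT3G15450 (3.27 in CL, -3.24 in CV), AT2G31560 (-2.08, 1.80), DFR (-1.74, 2.66), the acyl-carrier-protein thioesterase gene FaTA (-1.62, 1.59), PORB (1.58, -2.09), LHCB4.3 (-2.14, 1.56), NRPE3B (1.86, -1.49) and AT4G01380 (-1.48 in CL, higher in CV). Changes from L to M and from L to H share the L array, so a gene in both sets is not 2 independent observations. The CVL signals of AT3G48230 (1.9), DFR (3) and AT4G01380 (3.6) were below the offset of 3.9. So were the CLH signals of AT2G31560 (2.9) and FaTA (2.2). The CLM signal of AT3G48230 (4) was near it. The sizes of the changes of these genes are therefore uncertain.

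**Figure D3:**
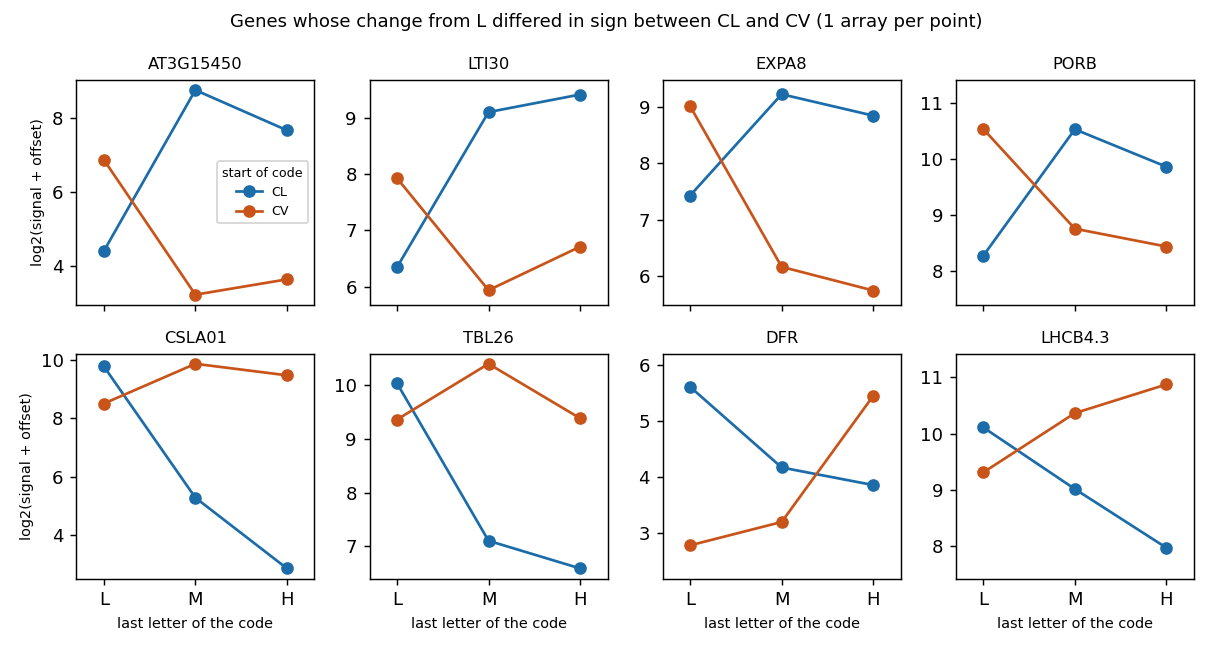
Log2(signal + 3.9) of 8 genes by the last letter of the code in CL (blue) and CV (orange), 1 array per point, without replicates. The lines cross for each gene: AT3G15450, LTI30, EXPA8 and PORB are higher in CV at L and higher in CL at M and H, CSLA01, TBL26 and LHCB4.3 the reverse, and DFR is higher in CL at L and M and in CV at H.

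The largest change of all named genes was that of CSLA01, a cellulose synthase-like gene, whose signal was 875.4 in CLL, 34.8 in CLM and 3.30 in CLH (log2 -4.51 and -6.93), and between 358.9 and 930.5 in CV. TBL26 was the next lowest in CL, with -2.93 at M and -3.44 at H. Other genes at the top within CL were AT4G23590 (2.65) and AT2G22510 (2.23) at M, and LTI30 (3.07), AT1G02190 (2.13), AT1G34270 (2.12) and the defensin-like gene LCR69 (2.08) at H. Next at the bottom were AT4G19750 (-2.50), AT1G61930 (-2.29) and AT4G10160 (-2.24) at M, and AT2G27420 (-2.70), AT4G18905 (-2.44) and AT4G08895 (-2.42) at H. Of these, all but AT4G18905 ended at signals between 1.4 and 2.7, below the offset of 3.9, as did CSLA01 in CLH. The CLL signals of AT4G23590, AT1G02190 and AT1G34270 (1.5, 1.9 and 2.6) were below it too. The sizes and order of these changes in CL are therefore uncertain. Within CV the highest at M were the auxin response gene IAA15 (2.75), AT4G02360 (2.41), AT2G21640 (2.28), AT4G26950 (2.23) and AT2G20790 (2.21), all from CVL signals between 0.9 and 2.5, below the offset of 3.9, so their sizes and order are uncertain. The highest at H were LEA4-5 (3.54), AT4G08570 (3.51), AT4G02360 (3.43), SAG29, a senescence-associated sugar transporter gene (2.70), and DFR; the CVL signals of AT4G08570, AT4G02360 and DFR were also below the offset. The lowest in CV at M were AT3G15450 (-3.66), EXPA8 (-2.85), AT4G26540 (-2.45), AT2G28870 (-2.32) and AT2G14900 (-2.16), and at H AT4G28780 (-4.02), EXPA8 (-3.27), AT3G15450 (-3.24), AT3G47800 (-2.97) and AT4G26540 (-2.84). Here too some signals were below the offset: AT2G28870 (2.8) and AT2G14900 (3.3) in CVM, and AT4G28780 (1.8), AT3G47800 (1.9) and AT4G26540 (2.3) in CVH.

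The cold, drought and abscisic acid list had a median change from L of 1.05 at M and 1.31 at H in CL (percentile 100 among random lists for each), and of -0.63 (percentile 0.22) and -0.34 in CV. Ribosomal protein genes changed by a median of 0.35 (percentile 100) at M and -0.66 (percentile 0) at H in CV, and by -0.09 (percentile 1.69) and 0.02 in CL. All 13 respiratory chain genes were higher at M than at L in CV (median 0.36, percentile 99.6), with the largest change in CYTC-2, a cytochrome c gene (0.99), and 5 of them in CL (median -0.04, percentile 26.4). Dehydrins and late embryogenesis abundant proteins had a median of 0.43 at H in CL (percentile 99.7) and 0.33 in CV (percentile 90.4). Of 9 auxin-linked genes, 8 were higher at H than at L in CV (median 0.62, percentile 99.0) and 5 in CL (median 0.23, percentile 94.7).

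Across probe sets, which are not independent replicates, the changes from L to M in CL and in CV had a correlation of -0.24, and those from L to H a correlation of 0.003. At M, 97 probe sets were at least 2-fold changed in both starts in opposite ways and 29 in the same way, where independent lists would give 19.6 and 19.5. At H the counts were 98 and 83, where independent lists would give 45.6 and 43.2. Dim probe sets carry much of these counts: without the lowest 50% of probe sets 65 were opposite and 2 alike at M, and 52 and 30 at H. These differences have no replicate check.

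On average the arrays resembled each other most within a start. There were exceptions. CVH was closer to CLL (correlation 0.948, 605 probe sets at least 2-fold apart) than to CVM (0.948, 781) and CVL (0.940, 777). CVL was closer to CLM (0.948, 672) and CLL (0.946, 674) than to CVH. CLL had a lower correlation with CLH (0.944) than with CVL, CVM (0.945) or CVH. By probe sets at least 2-fold apart, only CVH of the CV arrays was nearer to CLL than CLH was (660). The mean correlation across probe sets was 0.951 over the 6 pairs of the same start, 0.936 over the 3 pairs of the same ending and 0.939 over the 6 other pairs. The closest pair was CVL and CVM (0.965, 461 probe sets at least 2-fold apart), and the farthest was CLH and CVM (0.924, 1078 probe sets). The first principal component held 35.6% of the variance and placed the CL arrays between -25.4 and -8.52 and the CV arrays between 4.89 and 30.9; the second, with 22.4%, set CVH (31.0) apart from CVL (-18.9).

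Control transcripts differed between arrays. The ratio of 3-prime to 5-prime signal of GAPDH was 3.76, 2.81 and 6.22 in CLL, CLM and CLH and 3.20, 3.39 and 5.50 in CVL, CVM and CVH, so that the arrays ending in H had the highest ratios in both starts. The same ratio of ubiquitin ran from 2.31 in CVH to 3.18 in CLH. The 3-prime ubiquitin signal was 7985, 6419 and 4963 on the CL arrays and 4078, 3742 and 3782 on the CV arrays. The 25S ribosomal RNA control ranged from 114.7 in CVL to 455.2 in CLL. The labels give background averages from 56.06 to 73.52, noise from 1.50 to 2.17 (highest in CVL and CVH), and 12 to 17 outlier cells on each array except CVH, which had 35.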

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

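The tests of the difference between changes, of signal brightness, of RNA integrity and of exchanged arrays were chosen after the results had been seen.

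Some changes from L had opposite signs in CL and CV, in a fit that has no replicate of either L code. With the M and H arrays of a start taken as 2 samples of 1 group, which differ in condition, and the lone L arrays assumed to vary like them, limma picked out 18 probe sets at an adjusted p under 0.05. All 18 had mean later changes of opposite sign, 13 higher than L in CL and lower in CV, and 5 the reverse. The fit picks by the size of the difference, which favours opposite signs, and did not test the sign of either change. Of the 18, 7 were named genes: AT3G15450, with a change in CV minus that in CL of -7.27, EXPA8 with -4.67, LTI30 with -4.52, PORB with -3.84, CSLA01 with 6.89, TBL26 with 3.71 and AT4G32340 with -2.83. The change of TBL26 in CV was only 0.53, with signals of 651.6 in CVL, 1340.2 in CVM and 662.7 in CVH. On simulated data this fit recovered 40 of 60 differences of 4 on the log2 scale, 5 of 60 of 2 and 1 of 80 of 1, with 3 calls among unchanged probe sets. With no intensity trend 0 of the 18 calls were kept, and with no filter 5. AT4G32340 is named after its values were seen. No array measures the spread of the L arrays, so the errors and p-values of this fit are not given, and the 18 are only the largest opposite differences relative to the spread between M and H.

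Among the genes named above for the largest opposite changes, 7 others had both later CL arrays on one side of CLL and both later CV arrays on the opposite side of CVL, and were not among the 18; other named genes with this pattern are not listed here. Their differences were 3.46 for AT2G27420, 3.04 for AT3G48230, -2.01 for AT1G27210, 3.12 for DFR, 2.70 for FaTA, 2.92 for LHCB4.3 and 2.45 for AT4G01380. The CLH signals of AT2G27420 (2.7) and FaTA (2.2) were below the offset of 3.9. So were the CVL signals of AT3G48230 (1.9), DFR (3) and AT4G01380 (3.6). Those of AT1G27210 in CLL (6.2) and CVM (5.7) were not far above it. The sizes of the differences of these genes are therefore uncertain. LHCB4.3 had signals of 247.5 or more on every array. A second probe set of AT1G27210 had the same opposite signs at M and negative changes in both starts at H.

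The scaling of the arrays does not account for the opposite signs, since quantile normalization left 99 probe sets at least 2-fold changed in opposite ways at M and 89 at H (97 and 98 before), with 17 of the 18 still picked out. An exchange of the CLL and CVL arrays stays open: of 220 probe sets at least 2-fold apart between CL and CV the same way at M and at H, 56.4% differed that way at L, whereas an exchange with no effect of the endings would put nearly all of them the opposite way, and stable differences between the starts nearly all the same way. Other values follow the labels at L, where 42 of 43 ribosomal protein genes were higher and all 6 ATG8 genes lower in CV, and where CVL was closest to CVM (correlation 0.965) and CLL to CLM (0.956). Some pairs of arrays go the other way: CLL was closer to CVH (0.948) than to CLH (0.944), and CVL was closer to CLM (0.948) than to CVH (0.940). The values that follow the labels do not forbid an exchange, since each start has its own unknown change from L. An effect of the conditions that runs in opposite directions in the 2 starts may give the same values, and no array replicates either L code, so these explanations cannot be told apart.

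The ribosomal protein genes were higher in CV. A trend with signal brightness is argued against by random lists of the same brightness, among which the list's median had percentile 100. One array alone is argued against by leaving out each in turn: the median change stayed at or above 0.47, the value without CLM or CVM, and between 41 and 42 of the 43 genes stayed higher in CV. With the ending as a block, leaving out an array also takes the other array of its ending out of this comparison. Leaving out either of the 2 arrays of an ending therefore gave the same change, so these are not all separate checks. RNA integrity stays open, since the 3-prime to 5-prime ratios overlapped between CL and CV for both of 2 controls, but 3 arrays against 3 are too few to exclude a smaller difference. A biological difference between the starts, and a difference in how their arrays were processed, may each give this pattern and were not tested.

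Between CV and CL, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, called as many as 2 probe sets, and the highest other split called 0. In 6 of the other splits both arrays of an ending fell on the same side, which left 1 ending to part the sides; the 3 that parted every ending, as the real one does, had between 63 and 281 probe sets at an unadjusted p under 0.05, and the real one 748. With 10 splits the share cannot fall under 0.05.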

How the results depend on the processing

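The test of opposite changes from L, and leaving out arrays for the ribosomal list, were added after the data had been seen; the cause of each change below was not tested. With 5 arrays 1 residual degree of freedom is left, the lone arrays are assumed to vary like the others, and the simulated fits made false calls. Leaving out 1 array gave between 1 and 257 calls for CV against CL, 0 and 38 for M against L, 0 and 64 for H against L, and 0 and 10 for H against M. Leaving out CLM, CLH, CVM or CVH gave between 24 and 70 for the opposite changes, which need both L arrays. CV against CL had 0 calls with no intensity trend and 0 with no block, and 2 under the other settings with 6 arrays. Opposite changes had 5 calls with no filter and 0 with no intensity trend, and between 14 and 24 under the other settings with 6 arrays. The called lists fell to 0 with an estimated correlation and to 0 with fry for each of the 4 contrasts, and to 0 for M against L after quantile normalization.

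The correlation of the CL and CV changes at M was -0.16 with no filter, -0.42 without the lowest 50%, -0.20 with a smaller offset and -0.34 with 4 times the offset; at H it was -0.049 without the lowest 50%. Same-way changes numbered 58 at M and 125 at H with no filter, 2 and 30 without the lowest 50%, 60 at M with a smaller offset, and 2 and 18 with 4 times the offset. Opposite changes of at least 2-fold numbered 52 at H without the lowest 50%, and 46 at M and 45 at H with 4 times the offset. The mean correlation of arrays of different starts was 0.952 with no filter; with a smaller offset the means were 0.940 within and 0.927 between starts, and with 4 times the offset 0.965 and 0.952. Of the values of the named genes over the settings, 36 of 253, 0 of 121, 2 of 122 and 5 of 124 passed the test in the 4 contrasts, each with CLL, CVL, CLH or CVH left out. Signals near the offset limit what can be read from dim genes.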

Other observations

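Of the lists with 1 or 2 measured genes, the genes were as follows, with log2 changes from L at M and at H. The clock gene GI had 0.36 and 1.04 in CL and -0.07 and 0.04 in CV. MCCA, of the dark-inducible list, had a change between CV and CL of -0.81 (SE 0.50). APL3, a subunit of the starch enzyme ADP-glucose pyrophosphorylase, had -1.01 and -0.90 in CL and 1.53 and 2.36 in CV, again opposite in sign. The antenna-like protein gene LIL3:1, of the photoprotection list, was higher in CV by 0.45 (SE 0.22), and so were the photorespiration genes AT1G11860 (0.39, SE 0.23) and HPR (0.35, SE 0.20). None of these passed the test. THI2.1 and DFR were the only measured members of the jasmonate and flavonoid lists.

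The other lists tested between CV and CL were not called. Their median log2 changes were -0.44 for 3 glutathione transferases (adjusted p = 0.066; GSTF3 -2.11, GSTU18 -0.44, GSTU16 -0.07), 0.18 for 13 respiratory chain genes (adjusted p = 0.078), 0.35 for 8 cell division and histone genes, -0.31 for 11 dehydrins and late embryogenesis abundant proteins, -0.06 for 4 chlorophyll and carotenoid genes, 0.11 for 3 antenna genes and 0.05 for 10 vacuolar ATPase genes. For the auxin-linked genes the median was -0.06, for floral, pollen and seed genes -0.25, for the Calvin-Benson cycle 0.21, for expansins and related enzymes 0.01, for glycosyltransferases -0.14 and for heat shock proteins -0.24. Defence-linked genes had -0.21, folding and secretory proteins -0.11, carboxypeptidases -0.15, the photosystem core -0.05 and senescence genes -0.19.

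The dehydrin gene COR47 also had opposite signs, with a mean later change of 1.54 in CL and -0.93 in CV, and its second probe set had 1.22 and -1.43. COR15B shared this, with signals of 1620.6, 3992.1 and 5030.9 in CLL, CLM and CLH and 4786, 3278.6 and 1985.4 in CVL, CVM and CVH. The 11 genes of the dehydrin and late embryogenesis list did not share it as a set. The later change was higher in CL than in CV for 6 and lower for 5 (median difference 0.01, percentile 64.8), and LEA4-5 had changes of 0.86 in CL and 1.79 in CV. LCR69, which is not in that list, had 1.82 in CL and -0.77 in CV.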
